A study of Mus musculus with 6 samples.

How the data were processed

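RNA from the hippocampus of 6 mouse samples was measured, each on its own oligonucleotide array with 12488 probe sets, of which 66 are controls. The study concerns mice that overexpress HuD, the neuronal RNA-binding protein encoded by Elavl4. Per the labels, all 6 samples are hippocampus total RNA, and no label says which sample came from an overexpressing mouse and which, if any, from a control. All 6 samples were therefore left without a group. No genotype was inferred from the values, no comparison between genotypes was made, and no mean, SD or test treats the samples as replicates of a group. Samples are named by the number in their titles. Nothing in the labels says whether the samples came from single or pooled animals. The titles carry 2 further codes with no explanation of what they stand for. The first is 1 for all 6 samples, and the second is 2 for sample 2 and 1 for the other samples.

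The deposited values are signal intensity per probe set on a linear scale, 1 table for all 6 arrays. The scanner, the summary method, its version and the scaling step are not given in the sources used here. The values themselves show that no gene was centred and that all are above 0, with 0 missing values. The mean between the 2nd and the 98th percentile was 150.0 on every array, which is what scaling each array to a common target gives. The medians of the deposited intensity columns were 62.8, 61.4, 59.8, 63.3, 63.1 and 62.8 for samples 1 to 6. No pair of columns among the 15 was identical. Detection calls and scan dates were not used here. Values under the array median are thus not shown to be above background, and folds set against them are uncertain. For the same reason the measurement error of a single value and any batch are unknown, and the number of arrays limits the precision.

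Probe sets were named from the platform annotation, with symbols checked by gene identifier against the mouse RefSeq gene table (GRCm38.p6), which matched 10817 of them and changed 0 symbols. A single gene symbol was held by 10833 probe sets, several symbols by 396, and none by 1193. Only the first kind was used, covering 8251 genes. The assembly was used for names only. The genome build of the array design is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols were not named, which leaves some well-known genes unmeasured here.

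Each array was divided by its own median over the probe sets that are not controls, values under 0.2 of that median were set to it, and log2 was taken. A log2 value of 0 is thus the array median. Each gene was represented by its probe set with the highest mean. A gene counted as expressed when its median over the 6 samples lay above 0, which held for 4838 genes, and the floor was reached by 0 of their values. The difference between the highest and the lowest sample is called the range. No level of a gene is set against that of another gene.

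Gene lists, 35 in all, for cell types, hippocampal fields, neighbouring regions, stress and signalling responses, and mRNAs reported as bound by HuD were fixed before the data were examined, as were the rules, settings and alternatives except where said otherwise. A list needed at least 3 expressed genes, which 25 lists had. For each list 2 statistics were computed: the median range of its genes, and the coherence, which is the mean pairwise Pearson correlation of its genes over the 6 samples. Each was placed as a percentile among 10000 random lists of the same size, drawn from the expressed genes within 10 bins of mean level, and a list was called high at the 99th percentile or above. These percentiles describe these 6 arrays. They are not p-values, since genes are not replicates, and random lists would give 0.25 high calls among 25 lists for each statistic. For range that is too low a yardstick, since the lists as a whole lay high, with a median at the 91.85th percentile. The score of a list in a sample is the median, over its genes, of the log2 deviation from the gene's own median over the 6 samples. On simulated arrays with the real levels and spreads of the 4838 genes, and with 2000 random lists in place of 10000, lists of 7 genes sharing a common factor were called coherent in 26 of 28 cases, lists with a doubled SD were called high in range in 17 of 28 cases, and of 100 unchanged lists 1 was called coherent and 0 wide. Apart from the lists with a common factor, the simulated genes varied independently, whereas the first principal component of the real arrays held 29.5% of the variance. The rate for unchanged lists thus follows from the threshold and does not test real arrays. Lists of 3 genes were not simulated.

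Genes named in the text followed a fixed rule: the Elavl genes, the 25 expressed genes with the largest range, up to 4 members with the largest range in each list called high, the widest member of every other list, and the measured sex-linked genes. The further choroid plexus genes come from a list of 34 written before their values were examined, apart from any seen by chance. Other genes beyond these are named to describe a list's members or as later tests and were chosen after their values were seen. The alternatives were quantile normalization, no scaling, floors of 0.05 and 0.5, no expression filter, a filter at the 75th percentile, the mean of a gene's probe sets, unmatched random lists, Spearman correlation, and leaving out each sample. A floor at the array median was added after seeing the data. Only the relations in the closing section and the search for single samples that stand apart use the 6 samples as exchangeable units, although nothing in the labels says that they are independent or of 1 genotype. These relations were tested with exact permutation tests over all 720 orders of the samples, two-sided. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.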

Results

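The data are 6 array profiles of mouse hippocampus, numbered 1 to 6 and covering 8251 named genes, from a study of mice that overexpress HuD. HuD is the product of Elavl4, a neuronal RNA-binding protein known to bind AU-rich elements and to stabilise neuronal mRNAs such as that of Gap43. Because no label assigns a genotype, the results give the level of each named gene in each sample and the differences from sample to sample, and no sample is called transgenic or control. A difference between single samples has no replicate check.

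Elavl4 itself was measured by 1 probe set, at a signal of 84.6 in sample 1, 116 in sample 2, 96.2 in sample 3, 65.2 in sample 4, 82.5 in sample 5 and 110.4 in sample 6. After scaling, the highest sample (sample 2) was 1.83 times the lowest (sample 4), a range of 0.87 on the log2 scale. The median range of the 4838 expressed genes was 0.40 and their 95th percentile 0.95. The range of Elavl4 thus lay above the median gene and below the 95th percentile, a comparison not matched on level. In sample 4 its log2 value was 0.04, close to the array median. Whether this probe set reads the transcript of a transgene is not stated in the sources used here, so its level does not check the genotype of any sample. The other family members varied less. Elavl1, the ubiquitous HuR, was lowest in sample 1 and highest in sample 4, with signals from 135 to 203 and a range of 1.49-fold. Elavl3 ranged 1.30-fold and Elavl2 1.20-fold. The 4 genes did not move together (mean pairwise r of -0.10, 30.15th percentile of matched random lists, and a range at the 67.88th percentile).

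**Figure D1:**
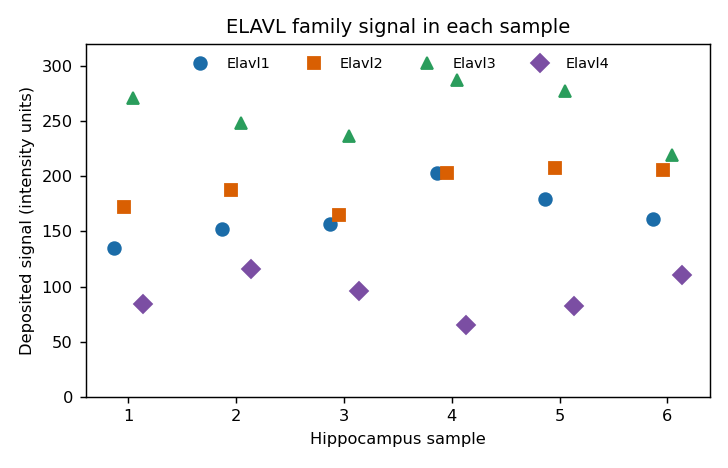
Deposited signal (vertical axis, linear intensity units from 0) of the 4 ELAVL genes in each of the 6 hippocampus samples (horizontal axis); each point is 1 array, and points are set slightly apart sideways for legibility. Elavl4 lies between 65.2 in sample 4 and 116 in sample 2, with intermediate samples in between.

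The mRNAs reported as HuD-bound differed from sample to sample more than random genes of like level, but not in concert. Of 11 genes on this list, 8 were on the array and 6 were expressed. Their median range was 0.58 against 0.33 for matched random lists (99.54th percentile), and their mean pairwise r was -0.09 (9.66th percentile). Camk2a, the alpha subunit of the calcium/calmodulin-dependent kinase of excitatory synapses, ranged most, 3.51-fold, from a signal of 274.8 in sample 3 to 1016 in sample 5, and its second probe set had a like range (1.89 on the log2 scale against 1.81). In sample 3, where Camk2a was lowest, the 3' to 5' ratio of the pyruvate carboxylase control was highest (3.56), and it was lowest in samples 2 (1.57) and 5 (1.62), where Camk2a had signals of 845 and 1016. The beta-actin and Gapdh ratios were also lowest in samples 2 and 5 but highest in sample 1. Gap43, the growth-associated protein of axons, ran from 607.1 in sample 4 to 863.2 in sample 3 and 895.3 in sample 1, with a range of 0.59 on the log2 scale. Bdnf, the activity-regulated neurotrophin, was lowest in sample 1 at 534.7 and highest in sample 4 at 808.1. Ache, acetylcholinesterase, was lowest in sample 4 at 256.0 and highest in sample 3 at 362.7. The high call for range ended without sample 4 (95.04th percentile), with no expression filter (98.46) and with random lists not matched on level (93.0). Fixed lists in general varied more than random genes, their median lying at the 91.85th percentile, and with unmatched random lists 1 list was high in range, against 7.

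Myelin genes had the highest coherence percentile of the 25 lists, although their mean r was below those of the MHC class I (0.79) and cytosolic ribosome (0.72) lists, which have 3 genes each. All 7 expressed members (Mbp, Mog, Mag, Mobp, Cldn11, Ugt8a and Mal), which encode structural proteins of myelin or enzymes of its lipids, had their lowest value in samples 1 and 2, 4 of them in sample 1 and 3 in sample 2. Their mean pairwise r was 0.69 (99.99th percentile), and their median range was 0.61 against 0.35 for random lists (99.47th percentile). Ugt8a, the enzyme of galactocerebroside synthesis, ranged 2.70-fold, from 45.2 in sample 1, under the array median, to 122.7 in sample 5, and 1.94-fold with values under the array median counted at it. Cldn11 ranged from 281.0 in sample 1 to 546.9 in sample 4, Mag from 287.4 in sample 1 to 527.4 in sample 3, and Mog from 140.3 in sample 2 to 209.2 in sample 3. Second probe sets of Cldn11 and Mag, under the array median in all samples, ranged by 0.28 and 0.55 on the log2 scale, against 0.95 and 0.94, and ran otherwise, with Cldn11 highest in sample 1 and Mag lowest in sample 3. With the mean of probe sets the range call ended (74.24th percentile), as it did with unmatched random lists (95.79). The list scores were -0.28, -0.20, 0.13, 0.18, 0.14 and -0.06 for samples 1 to 6. The thalamus and habenula list, fixed as a sign of neighbouring tissue, had scores of -0.34, -0.15, 0.09, 0.15, 0.19 and -0.06 in the same samples (range at the 97.10th and coherence at the 95.28th percentile, neither called high). Its widest member was Lef1, a transcription factor of Wnt signalling, at 105.5 in sample 1 and 220.2 in sample 4. Without sample 1 the myelin list fell just under the coherence threshold (98.84th percentile).

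The MHC class I list also passed both thresholds, on 3 expressed genes only. B2m, the shared light chain, and the heavy chains H2-D1 and H2-K1 were, after scaling, all highest in sample 3 and lowest in sample 4. B2m had signals of 618.4 and 377.0 in these samples, H2-D1 had 290.1 and 172.0, and H2-K1 had 285.8 and 229.5. Their mean pairwise r was 0.79 (99.43rd percentile) and their median range 0.79 (99.44th percentile). The names of the H2-D1 and H2-K1 probe sets mark them as shared within a gene family, so neither is specific to its gene. Their other probe sets differed in range, with 0.64 and 0.05 for H2-D1 against 0.83, and 2.19 and 1.13 for H2-K1 against 0.40. The H2-D1 probe set with a range of 0.64, also marked as shared, was lowest in sample 4 (1.29 on the log2 scale). After scaling only, it was highest in sample 3 (1.93), with sample 2 close (1.92). The H2-K1 probe set whose name marks no sharing lay under the array median in all samples and did not show the pattern, being lowest in sample 5 and highest in sample 6. In sample 3, where the list was highest, the 3' to 5' ratios of the transferrin receptor (3.47) and pyruvate carboxylase (3.56) controls were also highest and the beta-actin 3' signal lowest (6690). The beta-actin and Gapdh ratios were instead highest in sample 1. The coherence call ended without sample 1 (98.65), sample 3 (92.91) or sample 4 (96.42) and with no expression filter, where Tap1 and Psmb8 entered the list (42.93rd percentile). It ended too with the mean of probe sets (96.80) and with Spearman correlation (97.40). The range call ended without sample 3 (85.46) or sample 4 (94.58), with quantile normalization (98.39), with the mean of probe sets (88.06), with no filter (66.76) and with unmatched random lists (97.39).

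Genes of meninges and fibroblasts showed wide differences, with a median range of 0.73 against 0.35 for random lists (99.92nd percentile) and a mean r of 0.32 (92.66th percentile). Ptgds, the prostaglandin D synthase that meninges and choroid plexus share with oligodendrocytes, went from 1317 in sample 5 to 4699 in sample 2, a 3.67-fold range, and 2 further probe sets ranged by 1.32 and 1.46 on the log2 scale. The names of all 3 Ptgds probe sets mark shared or less specific probes. Dcn, the matrix proteoglycan decorin, ranged 2.31-fold, from 314.6 in sample 4 to 703.3 in sample 2. Slc6a13, a GABA transporter of meninges, ranged 1.79-fold, and Igf2, the insulin-like growth factor of meninges and choroid plexus, ranged 1.54-fold. Of the list's 6 expressed genes, 4 had, after scaling, their highest value in sample 2, 1 in sample 1 and 1 in sample 6. The list's scores were 0.24, 0.32, -0.17, -0.15, -0.20 and 0.27.

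Among the neuronal lists, those of glutamatergic neurons, interneurons and axon growth were called high in range and not in coherence, and those of CA1, dentate granule neurons and synaptic vesicles in neither. For the glutamatergic list (6 genes) the median range was 0.68 (99.71st percentile) and the coherence stood at the 69.57th percentile. Gria1, an AMPA receptor subunit, ranged 1.90-fold, from 893.3 in sample 3 to 1793 in sample 4, although its second probe set had a range of only 0.37 on the log2 scale. That probe set was highest in sample 3 after scaling only, and in sample 5 (750.1) in deposited signals. Grin2a, an NMDA receptor subunit, ranged from 64.9 in sample 3 to 129.7 in sample 5. Neurod6 ranged 1.73-fold and Grin2b 1.48-fold. Grin2a, Grin2b and the first Gria1 probe set were lowest in sample 3, where the 3' to 5' ratios of the transferrin receptor (3.47) and pyruvate carboxylase (3.56) controls were highest. Neurod6 (403.4) and, after scaling only, Neurod2 were highest in that sample. For GABAergic interneurons (11 genes) the median range was 0.57 (99.26th percentile, coherence 84.09th). After scaling, 7 of the 11 were highest in sample 3, the array with the highest of these control ratios. The beta-actin and Gapdh ratios did not single out sample 3, being highest in sample 1 (1.27 and 0.86). In deposited signals, of these 7 only Npy, Calb2 and Lhx6 were highest there. Gad2, a GABA-synthesising enzyme, ranged 2.03-fold and Lhx6 1.81-fold, or 1.27-fold for Lhx6 with values under the array median counted at it. Reln, the extracellular protein reelin, ranged 1.75-fold, from 163.4 in sample 4 to 283.8 in sample 1, and Calb2 1.62-fold. For axon growth and neuronal cytoskeleton (10 genes) the median range was 0.58 (99.82nd percentile, coherence 36.30th). Gap43 and Mapt are on both this list and the HuD-bound list, so the range calls of these lists are not separate. Map2, the dendritic microtubule protein, ranged from 150.4 in sample 1 to 304.1 in sample 5. Dpysl3 ranged 1.90-fold (1.32-fold with values under the array median counted at it), Stmn1 1.58-fold and Nefm 1.56-fold. The glutamatergic call ended without sample 1 (98.54) or sample 3 (96.20), the interneuron call without sample 3 (98.60) or sample 4 (85.96), and the axon call without sample 1 (82.17), sample 2 (91.24) or sample 4 (98.69). With the mean of probe sets all 3 ended (93.94, 98.66 and 96.59), as they did with unmatched random lists, and the interneuron call ended also with quantile normalization (98.30), no scaling (98.78) and no filter (98.58).

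The other 18 lists with enough genes were not called high for either statistic. Astrocyte genes lay just under the threshold for range (98.99th percentile, coherence 44.37th), with Fgfr3 the widest at 5.07-fold, or 2.32-fold with values under the array median counted at it. The astrocyte list passed the threshold with quantile normalization (99.89), no scaling (99.78) and the mean of probe sets (99.18) and fell to the 26.74th percentile without sample 3. Immediate early genes had a range at the 90.44th and a coherence at the 97.28th percentile, with 6 of 9 genes highest in sample 1, and Fos, their widest member, ranged from 90.8 in sample 3 to 210.3 in sample 1. Mitochondrial respiration genes ranged little (8.32nd percentile, coherence 97.94th), with Uqcrb the widest at 1.53-fold. Ranges were also small for heat shock genes (12.50th percentile, Hsph1 1.26-fold). Microglia lay at the 15.24th percentile (Cx3cr1 1.40-fold), but at 51.95 with the mean of probe sets, 50.51 with no filter and 55.08 with the filter at the 75th percentile. The mural cell list (range 88.38th, coherence 91.42nd percentile) was led by Tagln, a smooth muscle protein, at 109.0 in sample 2 and 47.7 in sample 4. Tagln ranged 2.36-fold, or 1.78-fold with values under the array median counted at it. The range percentile was 91.45 for CA1 pyramidal neurons (Wfs1, 1.69-fold), 91.94 for dentate granule neurons (Lct, 1.92-fold), 92.86 for clock genes (Dbp, 1.92-fold), 93.53 for glucocorticoid response genes (Sgk1, 1.56-fold), 91.85 for hypoxia response genes (Pfkfb3, 2.25-fold) and 91.83 for synaptic vesicle genes (Cplx1, 1.57-fold). It was 21.62 for endoplasmic reticulum stress (Pdia4, 2.15-fold), 41.52 for neurogenesis (Sox11, 1.83-fold), 37.14 for cholesterol synthesis (Sqle, 1.33-fold) and 88.50 for the cytosolic ribosome (Rps3, 1.44-fold). With values under the array median counted at it, Pdia4 ranged 1.73-fold and Pfkfb3 2.09-fold.

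**Figure D2:**
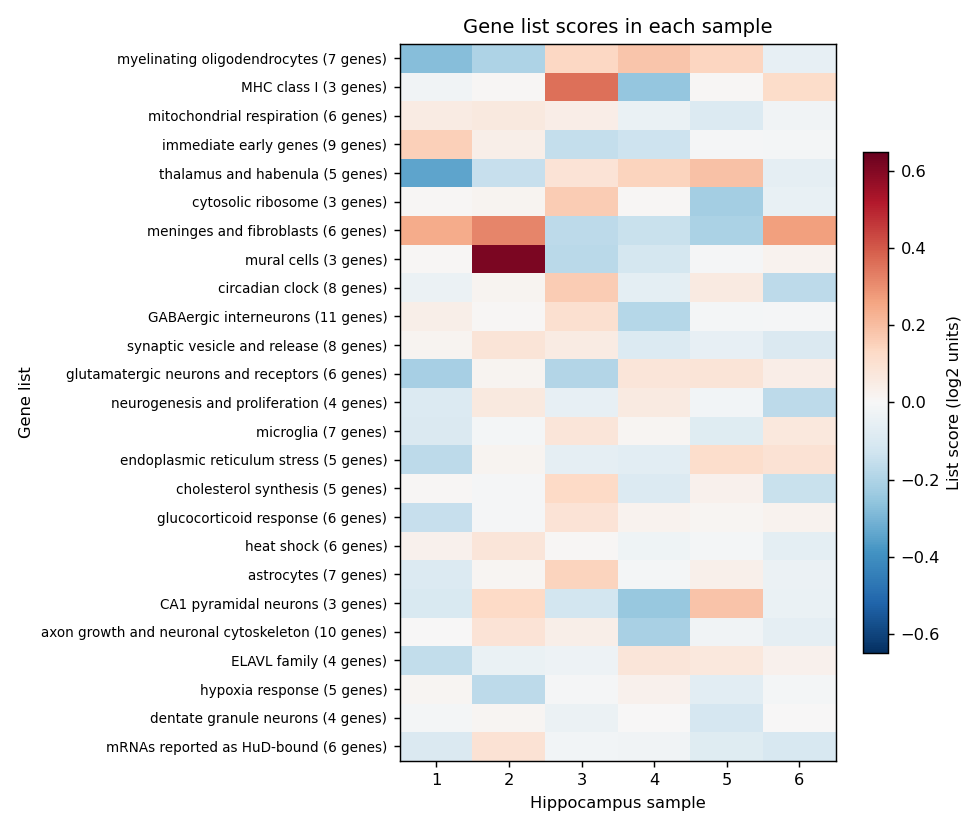
Score of each of the 25 gene lists (rows, ordered by coherence percentile) in each of the 6 samples (columns); colour gives the median log2 deviation of the list's genes from their own medians over the 6 samples, red above and blue below, and each cell rests on 1 array. The myelin row runs from -0.28 in sample 1 to 0.18 in sample 4 and the thalamus row from -0.34 in sample 1 to 0.19 in sample 5.

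The gene with the largest range was Ttr, transthyretin, the main secreted product of the choroid plexus. Its signal was 20.5 in sample 1, 44.9 in sample 2, 214.6 in sample 3, 1504 in sample 4, 482.1 in sample 5 and 1798 in sample 6, a measured range of 87.6-fold (6.45 on the log2 scale). The signals of samples 1 and 2 lay under the array median and are not shown to be above background. With these counted at the array median the range was 28.6-fold. Folr1, a folate receptor of the same epithelium, ranked among the widest genes too, at 22.7, 38.9, 51.4, 122.9, 126.5 and 162.1 in samples 1 to 6 (7.13-fold, or 2.58-fold with values under the array median counted at it). A second Folr1 probe set lay near the floor in all samples. The choroid plexus list had only these 2 expressed genes and was not tested with the filter. Without the filter it had 5 genes, with a median range of 1.94 (99.99th percentile) and a coherence at the 97.32nd percentile. Of the 3 added genes, Kl was lowest in sample 2 (37.2) and highest in sample 6 (146), and Aqp1 was highest in sample 1 (34.4), where Ttr was lowest, with 12.7 in sample 2 and 14.1 in sample 6. Cldn2 lay between 7.01 and 17.4, and the values of Aqp1 and Cldn2 were under the array median in all samples.

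**Figure D3:**
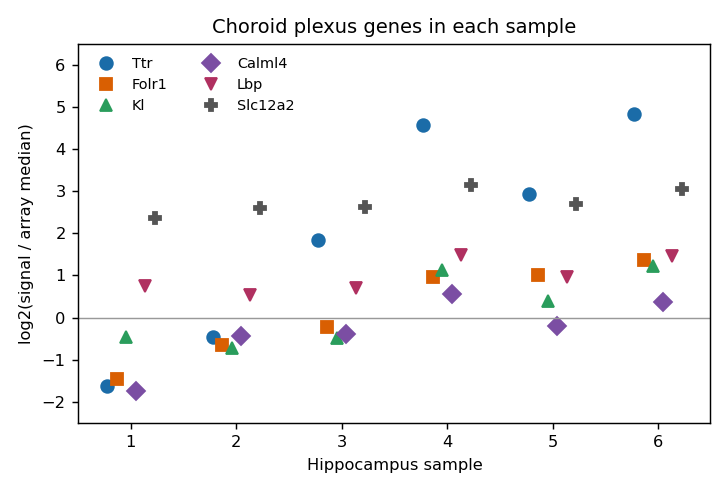
Level of 6 genes of the choroid plexus (vertical axis, log2 of signal over the array median, with the array median at 0) in each of the 6 hippocampus samples (horizontal axis); each point is 1 array, and points are set slightly apart sideways for legibility. Ttr runs from -1.62 in sample 1 to 4.84 in sample 6, and Folr1 from -1.47 to 1.37 in the same samples.

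The other genes among the 25 with the largest range were mostly dim. All 25 had at least 1 value under the array median, not shown to be above background, so the folds below are uncertain. For 21 of the 25 the median lay under 1 on the log2 scale, and 4 of the 25 probe sets have names that mark shared or less specific probes. Their order rests on those values: with values under the array median counted at it, 8 of the 25 stayed among the 25 widest. St3gal2, a sialyltransferase, had a measured range of 8.69-fold (lowest in sample 6) and 1.92-fold when so counted. Prrc2a had 8.15-fold (lowest in sample 3) and 1.80-fold, Get4 7.64-fold (lowest in sample 4) and 2.52-fold, and Pklr, a pyruvate kinase, 7.21-fold (lowest in sample 2) and 2.12-fold. Snrp1c-ps2 kept 5.37-fold of 6.15-fold and Icmt 3.84-fold of 4.44-fold. Zfpm2, Pfn1, H1f2, Otog, Gtf2f2, Yif1a, Hmces, Fgfr3 and Col9a1 had measured ranges between 6.85-fold and 5.02-fold, and Pus1, Olfr94, Cox6a2, Inha, Tanc1, Sh3bp1, Slc25a45 and Rab3a between 4.93-fold and 3.99-fold. For Prrc2a, Pklr, Fgfr3, Tanc1 and Rab3a a second, dimmer probe set did not show the same range. Of all 4838 expressed genes, 200 (4.13%) had a range over 1, that is, their highest sample was more than 2 times the lowest. With values under the array median counted at it, which also changes the choice of probe set for some genes, 126 of 4907 expressed genes (2.57%) did.

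Across all expressed genes the 6 profiles were close. The median absolute log2 difference between 2 samples was 0.15 over the 15 pairs, from 0.13 (samples 4 and 6) to 0.18 (samples 3 and 4), and Pearson's r across genes ran from 0.967 (samples 1 and 4) to 0.98 (samples 4 and 6). These r values are across genes, which are not independent replicates. The median distance to the other samples was 0.17 for samples 1 and 3, 0.15 for samples 2 and 4, and 0.14 for samples 5 and 6. The first principal component held 29.5% of the variance, with samples 1 (0.60) and 3 (0.40) at one end and sample 4 (-0.56) at the other. Control probe sets gave 3' to 5' ratios of 1.11 to 1.27 for beta-actin and 0.79 to 0.86 for Gapdh, both highest in sample 1. They were wider for the transferrin receptor (2.54 to 3.47) and pyruvate carboxylase (1.57 to 3.56), both highest in sample 3. The 18S ribosomal RNA 3' signal ran from 217 in sample 3 to 1143 in sample 2. The beta-actin 3' signal was lowest in samples 3 (6690) and 1 (8136) and reached 10332 in sample 4.

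Eif2s3y, a Y-linked translation factor gene, had signals between 80.9 and 95.5 in all 6 samples (1.17-fold), although the name of its probe set marks it as shared within a gene family. Xist, the RNA of the inactive X chromosome, lay at 6.24 to 14.3 in all 6. Kdm5d lay between 2.06 and 8.01 and Uty between 15.8 and 32.6, all under the array medians.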

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

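The genes chosen by the naming rule, the list scores and the control ratios and signals were checked for a single sample standing apart from the other 5 by a gap that, divided by the whole range, passes Dixon's 95% critical value, which chance gives for about 1 in 20 values. The 6 samples were treated as 1 set, although they may hold more than 1 genotype. Of 107 values tested, 15 stood apart, and over all expressed genes 285 (5.89%) did. Of the 15, 10 belong to the 25 genes chosen for their large range, a choice that favours such values. Numbers below are log2 deviations from the median of the other 5 samples.

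Those 10 genes were each low in 1 sample, with a value under the array median that is not shown to be above background. Sample 2 was low for H1f2 (-2.30), a linker histone, for Otog (-2.38) and for Col9a1 (-2.20), a collagen chain. Sample 4 was low for Yif1a (-2.22) and Pus1 (-2.14), and sample 5 for Olfr94 (-2.13) and Cox6a2 (-2.08). Sample 1 was low for Zfpm2 (-2.55), sample 3 for Prrc2a (-2.41) and sample 6 for St3gal2 (-2.75).

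Among the genes named from lists, Cldn11 and Map2 were low in sample 1 (-0.76 and -0.86), Grin2b was low in sample 3 (-0.45), and Tagln was high in sample 2 (0.81). The score of the mural cell list was also high in sample 2 (0.62), where Tagln and Rgs5 had their highest value, and Acta2 after scaling only (deposited signals of 117.7 in sample 2 and 120.0 in sample 1). Of the 15, 5 fell in sample 2, the sample whose title carries a differing code of unstated meaning. These 5 hold both Tagln and the score of the list that contains it, with H1f2, Otog and Col9a1, chosen for their range. No count per sample was made over all expressed genes, so no link to the code can be drawn.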

How the results depend on the processing

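Quantile normalization, no scaling and a floor of 0.05 kept every count within 1.5 times of its value, and the floor of 0.05 moved no expressed gene, so it tests nothing for those counts. The Elavl4 range was 0.83 to 0.87 under other scalings and floors. Of 76 named genes, the range moved by more than the median gene range for 16 with a floor of 0.5, 11 with the mean of probe sets 2 with a floor of 0.05, 26 with the floor at the array median, and for 3 to 9 without 1 sample. The number of genes with a range over 1 was 1063 with no expression filter and 44 with the filter at the 75th percentile, which test more and fewer genes, against 200 as reported, 126 with a floor at the array median (added after seeing the data), and 150 to 181 without 1 sample. At the stricter filter the median difference between samples was 0.125, and 1 of the 25 widest genes stayed among the widest. The count of lists high in range was 7, but 1 with unmatched random lists, 3 with the mean of probe sets, and 4 to 8 without 1 sample (4 without sample 4). The count of coherent lists was 2, but 4 with no filter, 4 with unmatched lists, and 1 to 3 without 1 sample (1 without sample 4). With unmatched random lists the range percentiles were 93.0 (HuD-bound), 98.3 (glutamatergic), 96.11 (interneurons), 95.79 (myelin), 97.39 (MHC) and 96.84 (axon). With the mean of probe sets they were 93.94 (glutamatergic), 98.66 (interneurons), 74.24 (myelin), 88.06 (MHC) and 96.59 (axon). With no filter they were 98.46 (HuD-bound), 98.58 (interneurons) and 66.76 (MHC). With quantile normalization they were 98.30 (interneurons) and 98.39 (MHC), and with no scaling 98.78 (interneurons). MHC coherence was 42.93 with no filter, 96.80 with the mean of probe sets and 97.40 with Spearman correlation. The cause was not tested. Without 1 sample, range percentiles ran from 95.04 to 99.91 (HuD-bound), 96.20 to 99.90 (glutamatergic), 85.96 to 99.67 (interneurons), 99.22 to 99.81 (myelin), 99.72 to 100 (meninges), 85.46 to 99.79 (MHC) and 82.17 to 99.95 (axon), and coherence from 98.84 to 100 (myelin) and 92.91 to 99.89 (MHC). Lists not called high passed the threshold under some settings: in range, astrocytes with quantile normalization, no scaling, the mean of probe sets, the floor at the array median (99.08) or without sample 2 (99.48), 4 (99.44), 5 (99.30) or 6 (99.01), and dentate granule neurons with no filter (99.10); in coherence, mural cells with no filter (99.34) or without sample 1 (99.48), meninges with no filter (99.45) or the mean of probe sets (99.80), immediate early genes with quantile normalization (99.72) or no scaling (99.81), mitochondrial genes with unmatched lists (99.42) or Spearman (99.26), and ribosomal genes with no filter (99.75) or unmatched lists (99.29). Of the calls, the meningeal range held under every alternative that gave a value, and the myelin coherence under all but the removal of sample 1. Of the 25 widest genes, 21 have a median under 1 on the log2 scale, near the array median, where signal over background was not measured here. No paired analysis was possible because no sample has a group.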

Other observations

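Other lists with too few expressed genes could be described only without the filter. Blood genes (4 genes, range at the 75.30th percentile), striatal genes (4 genes, 53.78th), endothelial genes (6 genes, 36.15th), interferon response genes (5 genes, 58.48th), CA2 and CA3 genes (5 genes, 17.01st), neocortical genes (3 genes, 90.48th) and sex-linked genes (4 genes, 0.47th) were not high in range. Their coherence percentiles were 13.34, 16.75, 69.49, 52.35, 20.98, 12.25 and 5.49. Pcp4 and Coch of the CA2 and CA3 list, and Kdm5d and Xist of the sex-linked list, lay at or near the floor throughout. The low range percentiles of these lists thus do not show stable expression. Of the expressed CA2 and CA3 genes, Bok ranged 3.64-fold, from 120.0 in sample 2 to 447.1 in sample 1, and Rgs14 1.21-fold. Markers of oligodendrocyte precursors and of ependyma had 2 measured genes each. Hba-a1, a haemoglobin chain, ranged by 0.58 on the log2 scale, and Penk, an opioid precursor abundant in striatum, by 0.35.

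In the tests that follow, that of the further choroid plexus genes was set down before their values were examined, apart from any seen by chance. The other 4 were chosen after the results were seen. No genotype is known for any sample, so no biological explanation was tested, and a difference between overexpressing and control mice stays open for each pattern.

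The wide range of Ttr may come from choroid plexus carried along in some dissections: of 34 further genes known from that tissue, 14 were above the array median in at least 1 sample, and their mean Spearman rho with Ttr was 0.44, against -0.04 for random lists (99.99th percentile, and 99.76 or higher without any 1 sample). Calml4, Slc12a2, Cab39l, Slc4a2 and Kl had rho of 0.8 or more, where random lists hold 0.40 such genes on average, while Atp1b1, Rbp4 and Msx1 had -0.71, -0.60 and -0.49 and Cd24a 0.09. Calml4 lay above the array median only in samples 4 and 6, and Kl only in samples 4, 5 and 6. The order of their other values is not shown to be above background. In checks added after the result was seen, the percentile was 99.57 (mean rho 0.34) for the 11 genes whose median lies above the array median in these hippocampus samples, 100 (mean rho 0.33) for all 27 measured, and 99.95 without Kl, which was also on the fixed list. Folr1 also followed Ttr, with r = 0.96 (exact permutation p = 0.00278, rho 0.94 with exact p = 0.0167, r = 0.86 without the 2 samples farthest from the median). Its values had been seen before this test was chosen, and 3 of them lie under the array median, so this p-value is no independent check. A fault of the Ttr probe set alone is argued against by the further genes above. Their test was set down beforehand for the dissection explanation only, and its use here was chosen afterwards. Regulation of these genes within hippocampal tissue stays open.

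The joint movement of the myelin genes may come from varying amounts of neighbouring fibre tracts and thalamus, but the thalamus genes did not all follow it. The score of the thalamus and habenula list followed the myelin score with r = 0.97 (exact permutation p = 0.00417, rho 0.94 with exact p = 0.0167, r = 0.92 without the 2 farthest samples), but among 24 lists set against the myelin score the adjusted p was 0.10, so this does not pass the correction. The relation is not specific to neighbouring tissue by rank, since the ELAVL family score had the same rho of 0.94 (exact permutation p = 0.0167, r = 0.80, adjusted p 0.30), and the immediate early genes (r = -0.88, exact p = 0.0222), the glucocorticoid response (r = 0.77, exact p = 0.025) and the meninges (r = -0.91, exact p = 0.0625) also had high r, with adjusted p of 0.20, 0.20 and 0.30, rho of -0.71, 0.54 and -0.66 (exact p = 0.136, 0.297 and 0.175) and, without the 2 farthest samples, r of -0.59, 0.16 and -0.96, against 0.22 for the ELAVL family. The first principal component is argued against as the whole cause, since with it removed the myelin coherence was 0.72 against 0.69 before, at the 100th percentile. The second component (21.3% of the variance, sample 3 at 0.77 and sample 1 at -0.63) was not removed. An array-wide axis of signal quality lying on that component was thus not tested. Of the 5 expressed thalamus genes, 3 had their lowest value in sample 1, where the myelin score was lowest. Tcf7l2 was lowest in sample 4 (153.8), where the myelin score was highest, and Tnnt1 in sample 6 (44.0). Of the 6 measured thalamus genes 5 are expressed in these samples anyway, so hippocampal cells may supply part of their signal, and a change in oligodendrocytes themselves stays open.

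Cross-hybridisation between H2-K1 and H2-D1, whose r was 0.87, may add to the coherence of the MHC class I list. B2m, which is not a heavy chain, had a mean r of 0.75 with the 2, at the 96.83rd percentile of its mean r with random pairs of genes. But B2m is 1 of the 3 genes whose coherence prompted the test, so this decides nothing and cross-hybridisation cannot be told apart from a joint change. The call depends on single samples, with a coherence at the 98.65th percentile without sample 1, the 92.91st without sample 3 and the 96.42nd without sample 4. Differences in strain background at the H2 locus were not tested.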
